A study of Arabidopsis thaliana with 4 samples.

How the data were processed

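Gene expression was compared directly between inflorescences of the Arabidopsis thaliana mutant apetala3 and wild-type inflorescences on 4 two-channel long-oligonucleotide arrays. Each array carried total RNA of both genotypes, 1 in each channel. Arrays 1 and 3 held the mutant RNA in channel 1 and arrays 2 and 4 held it in channel 2. The labels do not say whether the 4 arrays came from separate plants or extracts, so p-values measure only the spread between arrays, which may be technical. The number of arrays limits the precision of every value.

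The deposited values were log2 ratios of the 2 channels of each array, processed and normalized by the authors. The labels refer to an earlier publication for the method, and the scanner, background correction and normalization are not given in the sources used here. The scale was read from the values, which were symmetric about 0 and stopped at log2 ratios of 6.64 on either side, the log2 of 100. The columns were not centred exactly. Their medians as deposited were -0.11, 0.13, -0.09 and 0.08 for arrays 1 to 4. The upstream centring stays unknown.

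The arrays with opposite orientation correlated below 0 across genes, with a median Pearson r of -0.70 over the 4 pairs, so the deposited ratios followed the channels. The sign was turned by orientation so that every array read mutant over wild type. The labels do not name the numerator. The direction was to be set by AP3 and its partner PI, but 0 probes named either gene alone, so AP3 and PI were not analysed here. After the values were seen, the direction was instead set from the genes of the tapetum and pollen wall list, because apetala3 flowers form carpels in place of stamens. The probes naming members of that list had a median of -2.45 with channel 2 taken as the numerator, and this direction is called likely on that basis. That list is therefore no evidence of the direction. All counts can be read with the sign turned by exchanging higher and lower.

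Of 26933 spots, 26474 were gene probes. The remaining 424 empty spots and 35 control spots were left out of the comparison, and the empty spots were used as a background. The platform annotation paired 5784 gene probes with 1 gene and 7497 with several, and listed no gene for 13193. Of the probes with 1 gene, 5756 were matched by gene ID to the reference gene table of assembly TAIR10.1 and took their locus and symbol from it. No gene was named from a probe with several genes. Probes naming the same gene were averaged on each array. Of 276 genes with several probes, 78 had at least 1 probe past the threshold, 14 had all of them past it, and 3 had probes past it in opposite directions. The first and second probes correlated across these genes with a Pearson r of 0.55.

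Values within 1e-05 of the 100-fold limit were treated as not measured, a choice made after the data were seen. They numbered 268, 701, 587 and 531 gene probes on arrays 1 to 4. Genes and unnamed probes measured on at least 3 arrays were tested, 25588 in all, of which 5330 were named genes. The mean log2 ratio of each was tested against 0 with limma 3.58.1 (lmFit and eBayes, intercept only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors are limma's standard errors unless an SD is given. An exact two-sided sign-flip test over 4 arrays cannot give a p below 0.125, so no gene was tested that way.

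Gene lists were fixed before the data were examined. They covered floral organ identity and patterning, known AP3 and PI targets, petal development, tapetum and pollen wall, mature pollen and pollen tube, meiosis, carpel and ovule, photosynthesis and chlorophyll, flavonoids and phenylpropanoids, jasmonate and late stamen, floral terpenes, cell cycle, seed storage, heat shock and touch, circadian clock and housekeeping. Further lists were taken by keyword from gene names. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The genes named were AP3 and PI, the 10 highest and 10 lowest named genes past the threshold that were measured on all 4 arrays with the same sign, and up to 3 members of each list past the threshold, or the 2 with the largest absolute mean if none was past it. The other measured members of the tapetum, carpel and photosynthesis lists are given so that each list is complete. Genes named by other criteria are said to be so where they appear.

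The procedure was tested on simulated data drawn from the residual spread of 25008 genes and probes of this comparison, with 200 changed genes in each of 20 runs. It recovered 51.6% of genes changed by a log2 ratio of 1 and 86.5% of those changed by 2, and 4.67% of calls were false. The simulated spread was normal, independent between genes and centred on 0, without an offset shared by spots. The changed genes were also a far smaller share than the 18.5% called in the data. These rates therefore need not hold for the data. Alternatives changed the arrays used, the channel effect, centring, scaling, missing-value filter, test, threshold, probe averaging, array weights, direction and camera correlation. Keeping values at the limit as deposited was added after the data were seen.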

Results

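The series compared transcript levels between apetala3 and wild-type inflorescences of Arabidopsis thaliana. APETALA3 is a MADS-box transcription factor that specifies petals and stamens, and mutant flowers form sepals in place of petals and carpels in place of stamens. Both RNAs were hybridised together on each of 4 arrays, with the channels exchanged on 2 of them. All values are log2 ratios of apetala3 over wild type, in the direction called likely in the processing. The targeted gene AP3 and its partner PI were not analysed here, because 0 probes named either alone. The labels were therefore not checked against the targeted gene.

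The largest changes were decreases in apetala3. Of 25588 genes and unnamed probes tested, 4737 (18.5%) changed at a limma adjusted p under 0.05, with 2158 higher and 2579 lower. The split depended on the arrays, on centring and on array weights. Without array 1 there were 342 higher and 1476 lower, and with each array centred on its median 1065 higher and 2905 lower. With array weights the majority turned, with 3751 higher and 3056 lower. Decreases were larger, with a median log2 ratio of -1.36 among lower genes against 0.59 among higher genes. At least 2-fold, 1657 were lower and 247 higher. At least 4-fold, 836 were lower and 23 higher. At least 8-fold, 408 were lower and 0 higher. Among the 5330 named genes, 448 were lower and 486 higher, of which 294 and 60 changed at least 2-fold. Of all the called genes and probes, 4664 were measured on all 4 arrays, and all of these had the same sign on each array. The remaining calls lacked a value on an array, so they are not cases of opposite sign. A call over so few arrays itself selects for values of the same sign. The count is therefore no separate measure of agreement between arrays.

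The 10 lowest named genes had mean log2 ratios between -4.46 and -5.47, about 21.9-fold to 44.3-fold lower. The rule that named them required the same sign on all 4 arrays. The lowest was AT3G01250, at -5.47 ± 0.28 (SE, n = 4 arrays, limma adjusted p = 0.000574). AT1G66850, measured by 3 probes, had a mean of -5.09 ± 0.30, and AT3G26860 of -5.09 ± 0.31. AT3G52620 fell to -4.96 ± 0.27 and AT5G42170 to -4.85 ± 0.45. SWEET9, a sucrose transporter of the nectaries, was at -4.79 ± 0.25 (limma adjusted p = 0.000576). AT1G06260, with 3 probes between -4.20 and -4.78, had a mean of -4.57 ± 0.30. AT1G28375, AT1G24620 and AT1G15415 were at -4.51, -4.47 and -4.46. The probes of AT1G66850 ranged from -4.09 to -5.61.

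**Figure D1:**
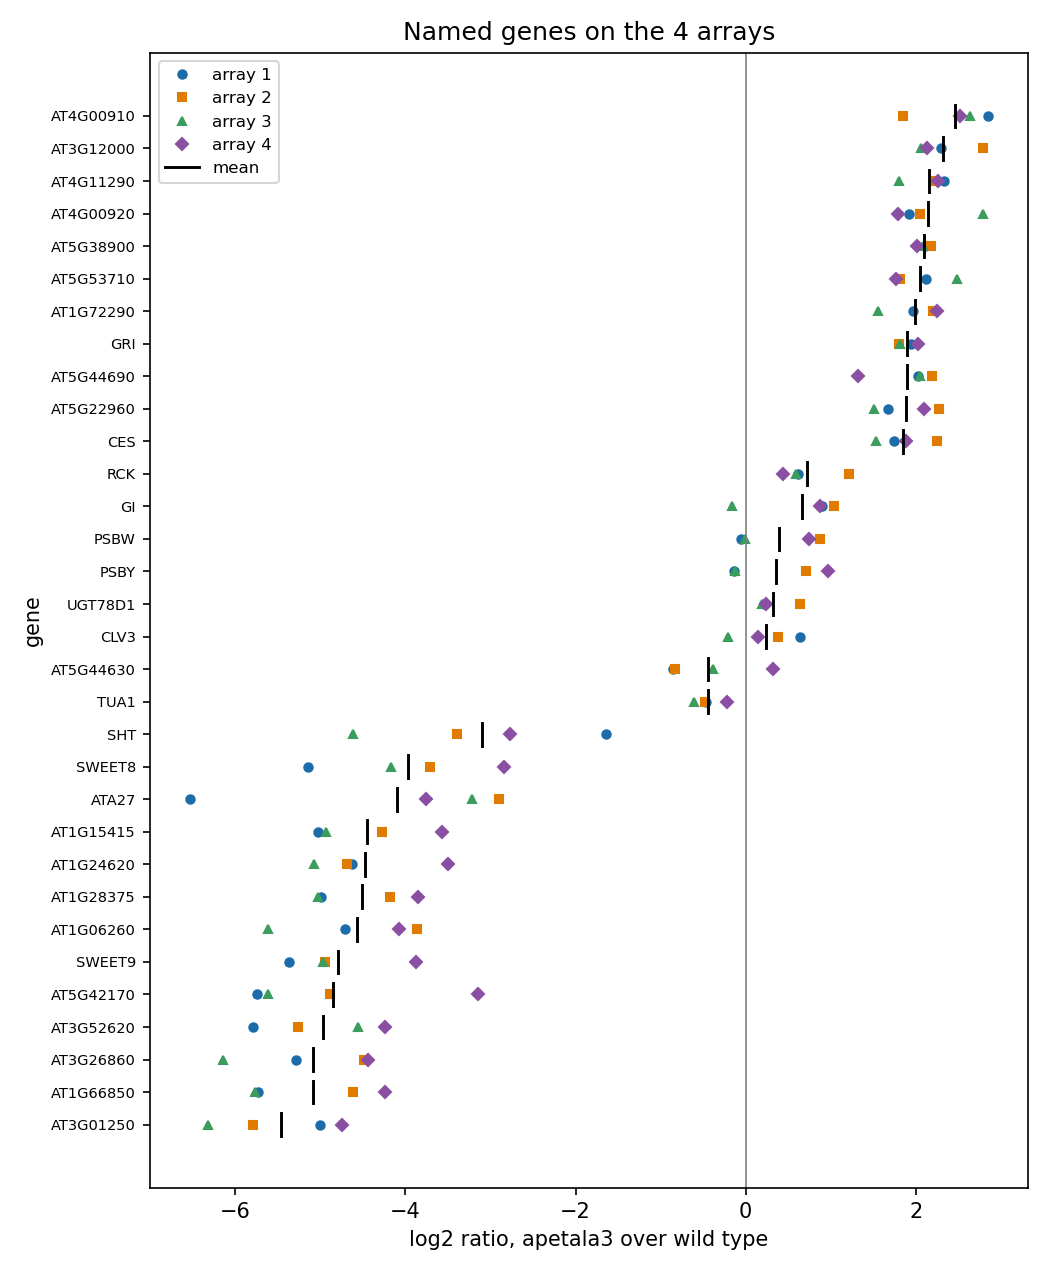
Log2 ratio of apetala3 over wild type (horizontal axis) for each gene named by the rule fixed before the data were examined (vertical axis), with 1 point per array and a black bar at the mean of the 4 arrays. The lowest gene, AT3G01250, has a mean of -5.47 and the highest, AT4G00910, of 2.46.

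The 10 highest named genes rose by log2 ratios of 1.89 to 2.46. The highest was AT4G00910, at 2.46 ± 0.18 (SE, n = 4 arrays, limma adjusted p = 0.00106). AT3G12000 followed at 2.32 ± 0.15, and AT4G11290 at 2.15 ± 0.12 with probes at 1.63 and 2.68. AT4G00920 was at 2.14 ± 0.19, and AT5G38900 was 4.27-fold higher with an SD of 0.07 on the log2 scale. AT5G53710 and AT1G72290 were at 2.04 and 1.99. GRI rose by 1.90 ± 0.10, AT5G44690 by 1.90 ± 0.17 and AT5G22960 by 1.89 ± 0.16.

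Genes of the tapetum, the anther layer that nourishes pollen, and of the pollen wall were mostly lower. Of the 47 genes on this list, 6 were measured by a probe naming them alone, and 5 fell, both over all genes and adjusted over the list alone. The list set the direction, so its sign is not independent evidence, but its size is measured. ATA27, an anther beta-glucosidase, was at -4.10 ± 0.61 (SE, n = 4 arrays, limma adjusted p = 0.0109). Its 2 probes differed, at -6.08 and -0.65, and the second, measured on 3 arrays, was not past the threshold on its own (limma adjusted p = 0.484). Array 1, at -6.53, rested on the first probe alone, and without it the mean was -3.29. SWEET8, a sugar transporter needed for the pollen wall, was at -3.97 ± 0.36 and SHT, a tapetal enzyme that makes spermidine conjugates, at -3.11 ± 0.46, a call lost without array 2. ATA20, an anther gene, fell by 2.76 and SPL, a regulator of sporogenesis, fell by 0.49. EMS1, a receptor kinase needed for tapetum formation, had a value of 0.07 and was not past the threshold. The median of the 6 was -2.93, with a camera adjusted p of 0.000261 at the preset correlation and an adjusted p = 0.194 with an estimated correlation. Fry, which tests whether the genes of a list move 1 way on balance without comparing them with other genes, gave an adjusted p of 0.00585. With values at the limit kept, ATA27 was at -2.45 and no longer past the threshold. Of 3 probes listing only members of this list but several genes, 2 were lower and 1 was higher, at 1.71.

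Pollen transcripts were lower where measured. Of 60 genes on the mature pollen and pollen tube list, 1 was measured by name. This was TUA1, an alpha-tubulin of pollen, at -0.44 ± 0.11 (SE, n = 4 arrays, limma adjusted p = 0.0408). It was no longer past the threshold without any 1 of arrays 1, 2 or 3. The same held with a constant channel effect in the fit (limma adjusted p = 0.0569) and with limit values kept (limma adjusted p = 0.0520). The 3 probes that list only members of this list, each with several genes, were all lower, with a median of -4.35. They stand for 2 sets of genes, since 2 of the probes list the same pair.

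Among carpel and ovule genes, those past the threshold were higher. Of 25 genes, 2 were measured by name. CES, also called HAF, a bHLH factor of the transmitting tract, rose by 1.85 ± 0.14 (SE, n = 4 arrays, limma adjusted p = 0.00117). INO, a regulator of the outer ovule integument, was at 0.20 and was not past the threshold. Of 6 further probes listing only members, 4 were higher and 0 were lower, with a median of 0.78. They stand for 3 gene pairs, each with 2 probes, and those higher for 2 of the pairs. Too few named members were measured for a set test.

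The remaining lists held few named members. RCK, a helicase of meiotic crossing over, rose by 0.71 ± 0.15 (SE, n = 4 arrays, limma adjusted p = 0.0314), a call lost without any 1 of arrays 1, 2 or 3. The RCK call was also lost with a constant channel effect in the fit (limma adjusted p = 0.0527) and with limit values kept (limma adjusted p = 0.0525). GI, a clock gene, was at 0.66 and UGT78D1, a flavonoid glycosyltransferase, at 0.32. CLV3, a meristem peptide, was at 0.24 and the floral terpene gene AT5G44630 at -0.44. None of these 4 passed the threshold over all genes, but GI and UGT78D1 did when adjusted over the list alone, each as the 1 measured member. Over all genes, GI passed without array 3, at 0.94, and AT5G44630 without array 4, at -0.69. None of the 3 measured photosynthesis genes passed the threshold, with PSBW at 0.39, PSBY at 0.35 and PSAN at 0.30 (camera adjusted p = 0.301, fry adjusted p = 0.0386). Among MADS-box genes of the agamous-like keyword, 17 were measured, with 3 higher, 2 lower and 12 not past the threshold (camera adjusted p = 0.246, fry adjusted p = 0.0386). Of 25 further probes listing only members of this keyword, each with several genes, 0 were higher and 5 lower, with a median of -0.21. Among the 5 is 1 of the pollen list's probes. The 5 share genes with each other, so they are not independent. The lowest of them was at -2.82, while another probe listing the same genes was at -0.21 and not past the threshold. Of 5 cytochrome P450 genes, 1 was higher (camera adjusted p = 0.149, fry adjusted p = 0.0127), and of 5 further probes listing only members, 0 were higher and 2 lower. Those 2 list the same gene pair, with the lowest value at -1.65. Fry makes no comparison with other genes, and the median of all genes and probes was itself above 0, at 0.115. A low fry p for a list with small values above 0 may therefore reflect that shift rather than the list. The 2 probes listing only meiosis genes and the 2 listing only photosystem genes were not past the threshold. The photosystem keyword had 3 measured members with 0 past the threshold (camera adjusted p = 0.301, fry adjusted p = 0.223), and the chalcone keyword had 1, at 0.16, also not past it. The lists of known AP3 and PI targets, petal development, jasmonate and late stamen, cell cycle, seed storage, heat shock and touch, and housekeeping had 0 named members measured. The same held for the keywords arabinogalactan, glycine-rich, lipid transfer protein, oleosin, pectinesterase, polygalacturonase and ribosomal protein.

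Changes were compared between the channel orientations. The mean of the 2 arrays with the mutant in channel 1 and that of the 2 with it in channel 2 correlated across 24697 genes and probes, with a Pearson r of 0.83 and a Spearman rho of 0.60. Genes are not independent replicates. PSBW had values of -0.06 and -0.0035 on arrays 1 and 3 but 0.88 and 0.74 on arrays 2 and 4, and PSBY had -0.14 and -0.13 against 0.71 and 0.96. Array 4 gave smaller changes, with a slope of 0.73 on the mean of the other 3 arrays over the called genes against 1.01 to 1.17 for arrays 1 to 3, and its Pearson r with them across genes was 0.62 to 0.69. A difference between the channel orientations passed limma's threshold for 0 genes, with 1735 (6.78%) at an unadjusted p under 0.05. Without limma's moderation of the variance the counts were 0 and 1630. This test set 2 arrays against 2, and its smallest limma adjusted p was 0.645. It therefore cannot exclude a channel effect on single genes.

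**Figure D2:**
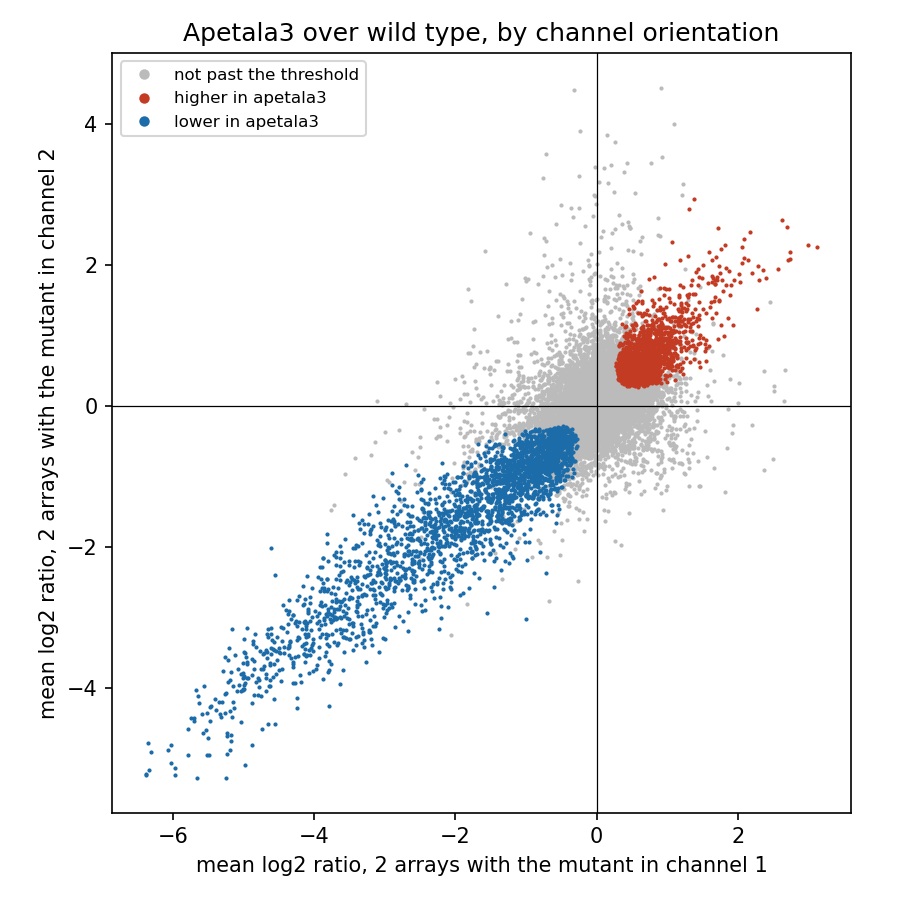
Mean log2 ratio of apetala3 over wild type on the 2 arrays with the mutant in channel 1 (horizontal axis) and on the 2 arrays with it in channel 2 (vertical axis), with 1 point per gene or probe, coloured by its call over all 4 arrays. The means correlated with a Pearson r of 0.83, and the lower genes extend farther from 0 than the higher ones.

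Empty spots had median log2 ratios of 0.76, 0.56 and 0.84 on arrays 1, 2 and 4 and of -0.27 on array 3. Those measured on at least 3 arrays had a median of 0.53, and 35 of 179 (19.6%, 95% Clopper-Pearson interval 14.0 to 26.1) were higher at the threshold, against 8.43% of genes and probes. Of the same spots, 5 (2.79%, interval 0.913 to 6.40) were lower, against 10.1% of genes and probes. The median of all genes and probes was 0.115. Decreases made up 73.2% of the calls after centring, against 54.4% before.

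**Figure D3:**
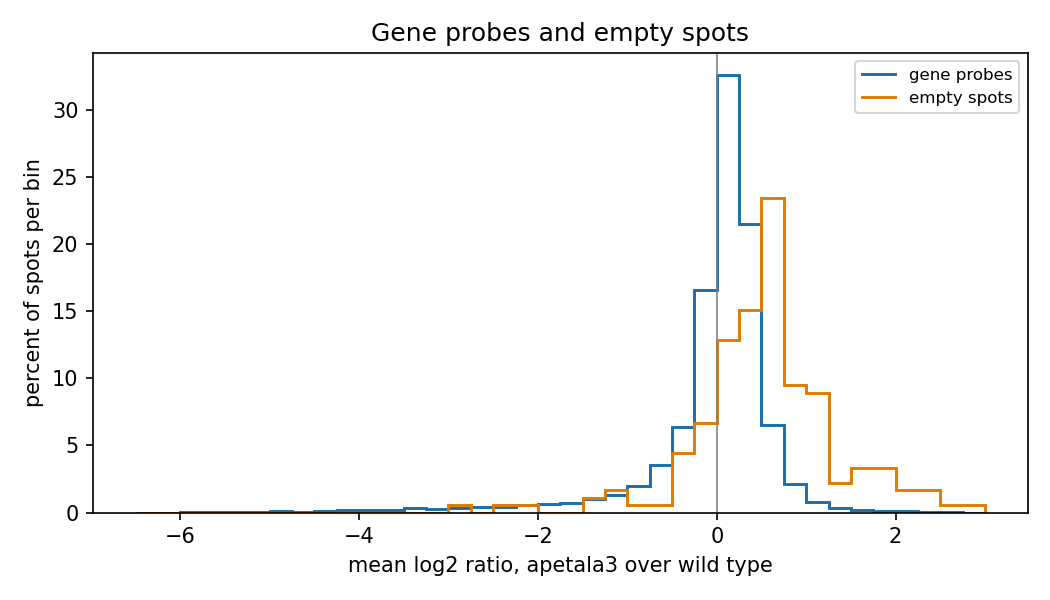
Percent of spots (vertical axis) in each bin of mean log2 ratio of apetala3 over wild type (horizontal axis), for gene probes and for empty spots measured on at least 3 arrays. Empty spots lie to the right, with a median of 0.53, and none of them lies below -2.91.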

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

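The tests of the limit values and of empty spots called higher or lower were chosen after their results were seen, and the test of the other channel orientation after related results were seen. The test of array 3 was written before its result was seen.

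On 4 of 56 named genes, 1 array lay far from the other 3, where chance gives about 2.8. GI had -0.17 on array 3, UGT78D1 had 0.64 on array 2, EXPB5 had -1.92 on array 4 and TRM23 had 1.05 on array 2.

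Among the empty spots, which carry no gene, 40 passed the threshold, 35 of them higher in apetala3. For increases under 2-fold, 15.1% of empty spots were called (95% interval 10.2 to 21.2) against 7.47% of genes and probes, so an offset shared by unhybridised spots may account for part of those calls, and it stays open which. For increases of at least 2-fold, 4.47% of empty spots were called against 0.963% of the long-oligonucleotide gene probes. Such an offset may therefore account for part of these calls too. For most of them it was argued against by array 3, where empty spots had a median below 0, at -0.27. The 252 gene probes called without array 3 and measured on it had a median of 1.05 there and a lower quartile of 0.68. The 9 empty spots called the same way had 0.14, with 6 above 0. Called or not, those at least 2-fold higher had 0.70 for gene probes and 0.06 for empty spots. With each array centred on its median, 178 increases of at least 2-fold were counted in place of 247, and 238 of the 247 stayed past the threshold of the test. A difference in organ makeup between the genotypes stays open for these increases, as untested.

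For decreases, the same background was argued against, since 2.79% of empty spots were called lower against 10.1% of genes and probes. A channel effect was argued against as well. Of genes called at least 2-fold lower with the mutant in channel 1, 99.2% were also below 0 on the arrays with it in channel 2. For genes called at least 2-fold higher, 90.2% were also above 0 there, so a channel effect was argued against less clearly for increases. With the orientations exchanged, the shares were 99.9% for decreases and 98.7% for increases. The authors' normalization was not tested as an explanation. The loss of stamens and petals known of apetala3 mutants, which the labels do not describe, stays open as a hypothesis. The list that set the direction cannot test it. The pollen and carpel lists did not set the direction. Their members and probes past the threshold were all lower for pollen and all higher for carpel, but too few were measured by name for a set test.

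Gene probes held 2087 values at the 100-fold limit, and 66 probes were at it on all 4 arrays. Of the empty spots' values 45.8% were at the limit, against 1.96% for the long-oligonucleotide gene probes, so signal near background in 1 channel may be the source. Transcripts present in 1 genotype alone were argued against as the general source. Of 1654 values at the limit whose probe was measured on other arrays, 13.8% had a mean there at least 2-fold the same way. The share was larger for the 23 values lower on array 1, at 43.5%, and the 19 lower on array 4, at 31.6%. By array and direction, it was 3.23% to 16.7% for the rest. The limit values were mostly higher in apetala3 on arrays 1, 2 and 4 and lower on array 3, and 65 of the 66 showed that order.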

How the results depend on the processing

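Alternatives were listed before the data were examined, except keeping the limit values as deposited. Without 1 array in turn, changed genes ranged from 1818 to 5028, with 342 to 2412 higher and 1476 to 2616 lower. The lowest counts were those without array 1 and the highest those without array 4. Without arrays 2 and 3 there were 2085 and 2793 changed, 495 and 868 higher, and 1590 and 1925 lower. Of those called without arrays 1 to 4 in turn, 1806, 2047, 2636 and 3848 were also called over all arrays. Array 4, whose loss raised the count, had the lowest array weight, 0.61. Array 1, whose loss lowered the count most, had the highest, 1.96, against 0.92 and 0.90 for arrays 2 and 3. The counts with array weights therefore lean on array 1. At least 2-fold, the ranges without 1 array were 1481 to 2125 changed, 173 to 367 higher and 1308 to 1758 lower. A plain t-test gave 1265 changed (502 higher, 763 lower), and at least 2-fold 679 (78 and 601). The 2 arrays with the mutant in channel 1 gave 2081 (447 and 1634). The 2 with it in channel 2 gave 873 (78 and 795), all at least 2-fold. An adjusted p under 0.01 gave 1645 (304 and 1341), and the 2-fold threshold 1904 (247 and 1657). Higher genes numbered 1430 with a constant channel effect, 1065 with centring, 3751 with array weights (3056 lower) and 1430 with limit values kept. With the sign turned, 1657 were higher and 247 lower at least 2-fold. The cause of the shifts with the arrays, test, channel effect, weights and limit values was not tested.

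The tapetum and pollen wall median stayed -2.93 with an estimated correlation, but its adjusted p rose to 0.194. On the arrays with the mutant in channel 1, PSBW was at -0.0325 and PSBY at -0.131, and the medians of the photosynthesis and photosystem lists were both -0.0325. Neither gene was past the threshold over all arrays or on those arrays, and neither list was by camera, though fry gave the photosynthesis list an adjusted p of 0.0386 over all arrays. The photosystem median passed on the arrays with the mutant in channel 2, at 0.83 (camera adjusted p = 0.0212), and the cytochrome P450 median on those with it in channel 1, at 0.58 (camera adjusted p = 0.0384). Over all arrays, the estimated correlation was 0.93 for the photosystem list and -0.11 for the cytochrome P450 list. With it, camera gave adjusted p of 0.571 and 0.376. Over named genes and alternatives, 763 values kept direction and side of the threshold, 73 lost it, 2 gained it and 2 turned. Most of these genes were chosen as past the threshold with the same sign on every array. For those genes a mean over fewer arrays could not turn, and the missing-value filters could not change the mean. Their kept direction is therefore no measure of robustness. The 2 values that turned were those of PSBW and PSBY, which were named from a list. AP3 gave no value under any alternative. No paired analysis was possible because each array is itself the comparison and there is 1 group. Signal over background was not analysed here, so which increases rest on dim spots is unknown.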

Other observations

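Genes with a functional symbol and the largest decreases were chosen after their values were seen. BGLU36, a beta-glucosidase family member, was at -4.40 ± 0.27 (SE) and RALFL25, a RALF-like signalling peptide, at -3.81 ± 0.23. The carboxypeptidase-like gene scpl38 was at -3.68, sks18 at -3.66, GH9A4, a family 9 glycosyl hydrolase, at -3.64, and PUB15 at -3.13. EXPB5, an expansin, was at -2.98, GH9B11 at -2.96, JMT, the jasmonic acid methyltransferase, at -2.96 with probes at -3.12 and -2.80, URE, the urease, at -2.96, and PAP20 at -2.86. These 11 were taken from genes past the limma threshold with the same sign on all 4 arrays. Neither property is therefore a result about them.

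Among the largest increases with a functional symbol, chosen in the same way, were 2 genes of the egg cell. EC1.1 and EC1.5, which encode small proteins secreted by the egg cell, were at 1.34 ± 0.20 and 0.97 ± 0.19. GOA, a MADS-box gene, was at 0.83 ± 0.19, a call lost with centring, where it had 0.73. CYP71B26 was at 1.21, GLC at 1.11, BCAT4, an aminotransferase of glucosinolate synthesis, at 1.05, and SCPL43 at 1.01. UGT73C1 was 2.30-fold higher. NdhN, a subunit of the chloroplast NDH complex, was at 1.13, with probes at 0.74 and 1.52. The second probe was not past the threshold on its own (limma adjusted p = 0.0554). GH3.1, CLE27, EXPA20 and TRM23 were at 0.97, 0.92, 0.90 and 0.80. The calls of EC1.5, GLC, BCAT4, NdhN and GOA were each lost without at least 1 of the arrays. The 5 agamous-like genes past the threshold were AGL77 at -1.09, AGL33 at -0.86, AGL103 at 0.60, AT1G30260 at 0.72 and GOA.

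The 384 probes whose names begin with GP, a code not explained in the sources used here, changed often. Of 370 measured on at least 3 arrays, 101 passed the threshold, 80 of them lower and 68 at least 2-fold lower. The share called was 27.3%, against 17.9% of the long-oligonucleotide gene probes. The excess was in decreases, at 21.6% against 9.77%, while 5.68% were called higher against 8.14%. These shares count probes, not genes, and lower genes such as AT1G66850 and AT1G06260 were measured repeatedly by GP probes. How much of the excess such repeats make up was not tested.

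A test chosen after its result was seen asked whether genes at least 2-fold lower lie side by side. Among 1159 adjacent pairs of measured genes in the gene order of assembly TAIR10.1, both members were at least 2-fold lower in 8, against a mean of 3.53 in 10000 permutations (one-sided permutation p = 0.0258). Of the 8 pairs, 2 shared AT3G29060. Genes at least 2-fold lower may lie side by side more often than by chance, as a hypothesis not tested on other data. Probes with several genes were not named, so similar neighbours were partly left out.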
